A study of Mus musculus with 6 samples.

How the data were processed

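Liver RNA of male C57BL/6 mice, an inbred laboratory strain, was profiled by RNA sequencing at 2 ages. Per the labels, each of the 6 libraries held equal amounts of total RNA from 3 mice, with 3 libraries from young and 3 from adult animals. The labels disagree on the young age, which is given as 3 weeks in the sample titles, as 3 to 4 weeks in the age field and as 1 month in the series title. The adult age is 6 months throughout. Livers were snap frozen, RNA was extracted with Trizol, and only RNA with an integrity number of 8 or more was used. Libraries were made with an Illumina TruSeq RNA kit and sequenced on a NextSeq 500 to an average of about 30000000 reads per library, per the labels' protocols. Whether the kit marked strand and the time of day at sacrifice are not given in the sources used here.

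The submitters' processing notes name TopHat2 2.0.11, Cufflinks 2.2.1, Cuffdiff without a version, and the mouse genome build GRCm38. The annotation release, the library normalization and the dispersion model are not given in the sources used here. The authors deposited 1 table of 32597 genes with the column layout of a Cuffdiff gene table. It holds 1 FPKM value (fragments counted on a gene, divided by transcript length and by the mapped fragments of the library) per gene and age group, so the authors had already combined the 3 libraries of each age. The deposited table also gives a log2 fold change, a test score, a p-value and a q-value (p adjusted for multiple testing) per gene, all from the authors' own test. A gene was called significant in the deposited table exactly where its q-value was under 0.05. The smallest deposited p-value, 5e-05, was shared by 554 tested genes, so these cannot be ranked among themselves. The smallest deposited q-value was 0.00189, while a Benjamini-Hochberg adjustment over the 16290 tested rows would give 0.00147, so the deposited values are not that adjustment; how they were adjusted is not given in the sources used here. The deposited log2 fold change has no pseudocount and is infinite where 1 age is at 0, and it differed from a log2 ratio recomputed from the 2 FPKM values by at most 5.06e-05 where both were above 0.

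No count and no value per library was used, because the table gives none. The sequencing depth behind each value is therefore unknown, no standard deviation can be given, and no test between libraries was possible in this work. The authors' q-value is the only measure of replicate error, and it rests on pools of mice, whose spread is smaller than that between single animals. The labels do not state whether the pools were processed on separate days.

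Genes were kept where the authors' test status was OK and the FPKM was at least 1 in at least 1 age group, which left 11741 genes. Another 16301 genes carried the status NOTEST and 6 the status LOWDATA. A gene was called where the authors' q-value was under 0.05, in the direction of its fold. Folds were computed here as log2((adult FPKM + 1)/(young FPKM + 1)). This scale understates the change of genes with low FPKM. A gene under 1 FPKM at 1 age passed the filter only through the other age, so its direction was fixed by the filter. Positions are those of the deposited table; 31943 of its gene identifiers were found in GENCODE M21, an annotation of GRCm38, and 99.9% of these overlapped the same gene's span there.

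Before the data were examined, 24 pathway lists and 13 cell type lists with 890 entries were fixed from textbook knowledge, together with the rule for naming genes, the processing alternatives and the thresholds. For each list, the number of members that rose, fell or were not called was counted, also with the authors' p-values adjusted over the list alone. The median log2 fold of a list was set against the central 95% of the medians of 10000 random lists of the same size, matched on mean FPKM in 20 bins. This describes where a list lies among the genes of these libraries and is not a test, since genes are not replicates. Random lists would put 1.85 of the 37 lists outside that range. On folds simulated for 11741 genes, 3.5% of 200 lists of 20 unchanged genes fell outside it. Of lists shifted by 0.25 and 0.5 on the log2 scale, 49.5% and 98.5% lay above it. The simulated genes were independent of each other, while members of a real list can move together. These shares are therefore not the rates for the lists used here.

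Named genes are the 12 largest rises and the 12 largest falls among called genes with a proper symbol (predicted and clone-based models left out), up to 4 called members of each list with the largest absolute fold (the 2 with the highest level where none was called), and Afp, H19, Igf2, Igf1, Mki67, Cdkn1a and Cyp7a1 in every case. A few genes that the rule takes are not reported here. Genes named outside this rule, after their values were seen, are marked as such. Gene families with near-identical copies can share reads, so the split between their members is uncertain. Among them are the Mup, Cyp2c, Cyp2a, Cyp2b, Cyp4a, Hba, Hbb, Saa, Hamp, Gsta, Slc22a and immunoglobulin genes. Genes that overlap another listed gene can share reads as well, among the named ones Dbp with Sphk2, Nr1d1 with Thra, Oat with Fgfr2, Igtp with Irgm2, Cxcl10 with Art3, Sult1a1 with Ccdc101 and H19 with Mir675.

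Alternatives were no filter on FPKM, a minimum of 5 FPKM, q thresholds of 0.01 and 0.1, an added 2-fold minimum, a Benjamini-Hochberg adjustment of the authors' p-values over the genes past the filter, 3 other scalings, a pseudocount of 0.1 and random lists without matching. Chosen after seeing the data were the male-biased list without Mup genes, the matrix list without cell type markers and the zonation lists without members of the metabolic lists. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for plots.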

Results

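The liver transcriptome of male C57BL/6 mice was compared between young animals of about 1 month, around weaning and before sexual maturity, and adults of 6 months. Each age was represented by 3 libraries of 3 pooled livers, or 9 mice per age. All FPKM values below are the authors' single values per age group from their deposited table, so they carry no standard deviation. A gene is said to rise or fall with age only where the q-value in the authors' deposited table was under 0.05. The q-values of the genes called and named below ran from 0.00189 to 0.0431 in the authors' deposited table. Of the genes listed, 11741 were tested by the authors and reached 1 FPKM at either age. The total was 762084 FPKM in young and 765940 in adult liver. Across genes, which are not independent replicates, log2(FPKM + 1) at the 2 ages correlated with Pearson's r = 0.968 and Spearman's rho = 0.960.

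Between the 2 ages, 469 genes rose and 408 fell, together 7.47% of the genes compared. The median change was 1.71-fold among the risen genes and 1.63-fold among the fallen ones. Among them, 150 rose and 81 fell by at least 2-fold. The genes with the largest rise were led by the major urinary proteins, small pheromone-binding proteins made by the liver: Mup12 rose from 5.45 to 108 FPKM, Mup7 from 390 to 5545, Mup17 from 63.4 to 840, Mup16 from 11.1 to 109.7, Mup11 from 159 to 1257 and Mup14 from 247 to 1864. The acetyltransferase-related gene Nat8 rose from 1.49 to 27.3 FPKM, the circadian transcription factor Dbp from 0.756 to 15.3, and the oxysterol hydroxylase Cyp7b1 from 24.4 to 204. The ubiquitin-like gene Ubd rose from 1.72 to 19.8 FPKM, the chemokine Ccl5 from 3.23 to 30.0, and the NADPH oxidase Nox4 from 3.33 to 29.5. The largest falls were those of the cytochrome P450 genes Cyp2b9, from 25.2 to 0.0974 FPKM, Cyp2c40, from 287 to 11.9, and Cyp2c69, from 70.4 to 2.79. The hepcidin gene Hamp2 fell from 463 to 29.7 FPKM, the hydroxyacid oxidase Hao2 from 9.19 to 0.0736 and Cyp2a4 from 15.0 to 0.711. The organic anion transporters Slc22a26 and Slc22a27 fell from 9.65 to 0.329 and from 8.20 to 0.487 FPKM. The light chain segment Igkv15-103, the alpha-globin gene Hba-a1 and the transcription factor Tcf24 fell from 13.6 to 0.822, from 277 to 50.2 and from 3.81 to 0.0491 FPKM. For Dbp the q-value in the authors' deposited table was 0.00494, and for the other genes named here it was 0.00189, the smallest in the table. A further 331 genes differed by at least 2-fold without being called, of which 276 were small RNAs and 227 were listed at 0 at one age.

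**Figure D1:**
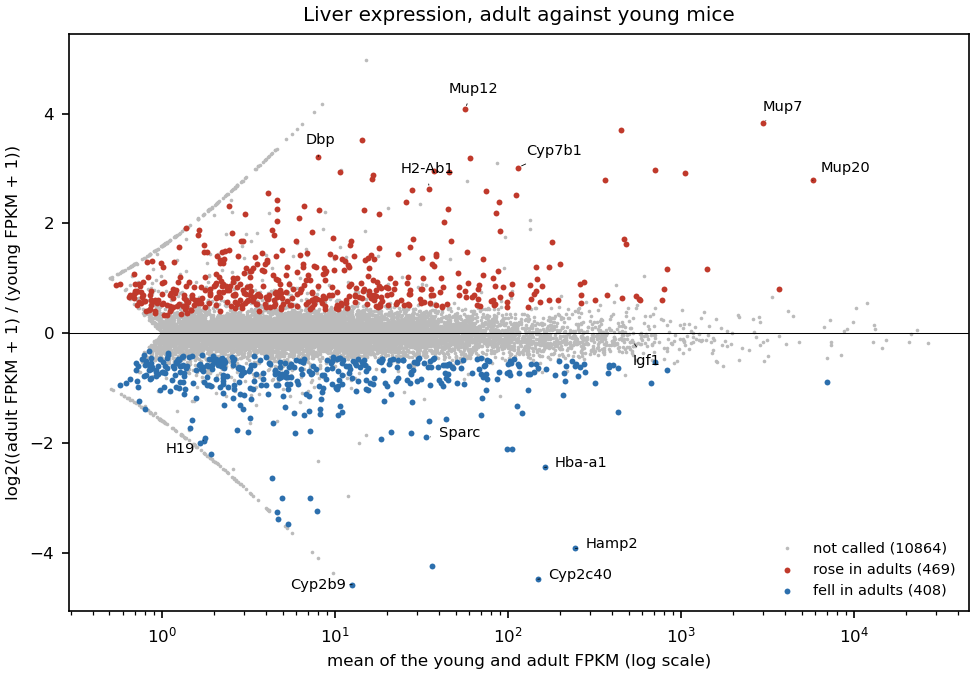
Each point is 1 of the 11741 genes compared, with the mean of the young and adult FPKM on a log axis against log2((adult FPKM + 1)/(young FPKM + 1)). Red points are the 469 genes that rose, blue points the 408 that fell, and grey points the 10864 that were not called; Mup12 and Cyp2b9 mark the upper and lower ends of the called genes.

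Called members of the lists of male-biased and female-biased mouse liver genes divided by that bias. Of 27 male-biased genes, 22 rose and none fell, with 24 risen when adjusted over the list alone. Of the 16 female-biased genes compared, 12 fell and none rose; adjusted over the list alone, 12 fell and 1 rose. The male-biased list had a median log2 fold of 0.88 and the female-biased list one of -1.46, each outside the central 95% of random lists of matched expression, which ran from -0.16 to 0.07 and from -0.14 to 0.17. Mup12, Mup7, Mup17 and Cyp7b1 had log2 folds of 4.08, 3.83, 3.71 and 3.02. Cyp2b9, Cyp2c40 and Cyp2c69 fell by 4.58, 4.48 and 4.24 on the log2 scale. On GRCm38, Mup12 lies on chromosome 4 at 60737383 to 60741326, Cyp7b1 on chromosome 3 at 18071950 to 18243338, Cyp2b9 on chromosome 7 at 26173411 to 26210661 and Cyp2c40 on chromosome 19 at 39767071 to 39812814. Without the Mup genes, whose copies can share reads, 14 of 18 male-biased genes rose and none fell, and the median log2 fold was 0.73.

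**Figure D2:**
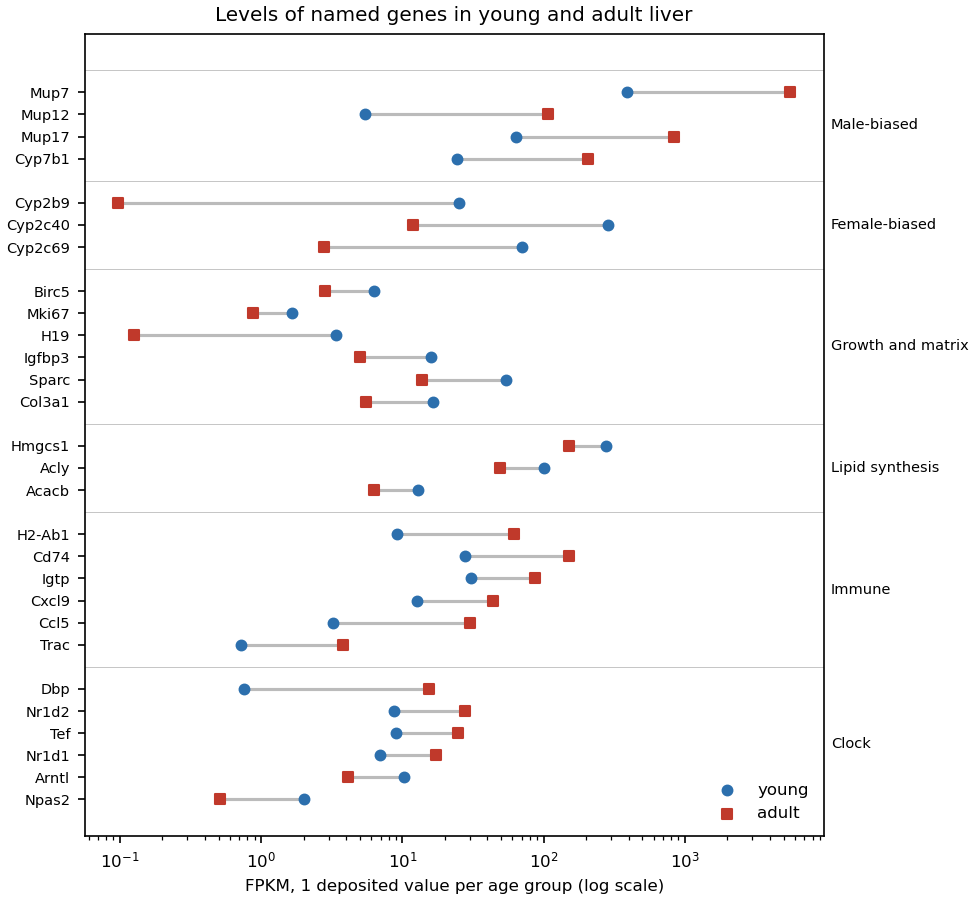
The FPKM of named genes is drawn on a log axis, with a circle for the young and a square for the adult value, 1 deposited value per age group and no error bar. Mup7 moved from 390 to 5545 and Cyp2b9 from 25.2 to 0.0974, while Arntl and Npas2 moved against Dbp among the clock genes.

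Some genes of growth and cell division fell with age. Of 38 cell cycle genes, 10 fell and none rose, and 20 fell when adjusted over the list alone. The apoptosis inhibitor and mitotic gene Birc5 fell from 6.34 to 2.84 FPKM, the replication helicase subunit Mcm6 from 7.52 to 3.48, the ubiquitin-conjugating enzyme Ube2c from 6.40 to 3.20, the ribonucleotide reductase subunit Rrm2 from 7.38 to 3.83 and the proliferation marker Mki67 from 1.64 to 0.878. Top2a, named after its values were seen, was at 5.88 and 2.84 FPKM with a q-value of 0.104 in the authors' deposited table. The median log2 fold of the list, -0.48, lay below the random range of -0.08 to 0.10. Of 12 fetal and imprinted growth genes, 5 fell and none rose, and adjusted over the list alone 8 fell and 1 rose. The imprinted noncoding RNA H19, on chromosome 7 at 142575529 to 142578143, fell from 3.37 to 0.126 FPKM, the glypican Gpc3 from 3.71 to 0.903, the trefoil factor Tff3 from 39.0 to 21.01 and alpha-fetoprotein, Afp, from 1.39 to 0.656. The median of this list was -0.52 against a random range of -0.18 to 0.17, but with a minimum of 5 FPKM, which left 4 members, it was 0.048. Igf2 was at 0.141 FPKM in young and 0.144 in adult liver. In the growth hormone and IGF list of 17 genes, 4 fell and none rose, while adjusted over the list alone 5 fell and 1 rose. Igfbp3 fell from 15.9 to 5.01 FPKM, Igfbp1 from 162 to 64.2, the signalling inhibitor Socs2 from 13.8 to 6.49 and Igfals from 54.9 to 37.1. Igf1 itself stood at 548 FPKM in young and 500.4 in adult liver, with a q-value of 0.987 in the authors' deposited table. The list median of -0.13 lay inside the random range but below that of unmatched random lists, and with a minimum of 5 FPKM it was -0.23 and below its range.

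Many extracellular matrix genes fell with age. Of 29 genes, 15 fell and none rose, and 20 fell when adjusted over the list alone. The matricellular gene Sparc fell from 53.9 to 13.8 FPKM, elastin, Eln, from 2.75 to 0.256, the collagen Col3a1 from 16.5 to 5.48 and periostin, Postn, from 9.66 to 3.99. The list median was -0.65 against a random range of -0.10 to 0.11. Without markers of the cell type lists, 15 of 28 fell and the median was -0.68. This took out no fallen gene, so it does not show whether the fall is separate from a change in cell types. Markers of mesothelium, the lining of the liver surface, also fell in all 4 compared, and in 4 when adjusted over the list alone: Msln went from 4.69 to 1.20 FPKM, Upk3b from 4.49 to 1.22, Gpm6a from 3.24 to 1.31 and Upk1b from 1.45 to 0.465. Their median was -1.09 against -0.36 to 0.50. Of 15 stellate cell and fibroblast markers, 1 fell (also 1 adjusted over the list alone), Acta2, from 1.38 to 0.494 FPKM; their median of -0.27 lay below the random range of -0.15 to 0.16. Of 6 cholangiocyte markers, 3 fell (3 adjusted over the list alone), the keratins Krt19, from 2.199 to 0.489 FPKM, Krt7, from 1.40 to 0.469, and Krt23, from 1.08 to 0.375. Their median of -0.42 lay below the random range of -0.26 to 0.33, but with a minimum of 5 FPKM it was -0.14 and lay inside its range. Of 19 endothelial markers, 2 fell (3 adjusted over the list alone), Lyve1, from 6.44 to 3.47 FPKM, and Oit3, from 11.3 to 6.82, with a list median of -0.22 against -0.12 to 0.13. The hepatocyte list had 1 fallen gene of 17 both over all genes and adjusted over the list alone, the plasma protein Ahsg, from 9035 to 4860 FPKM, and a median of -0.21 against -0.20 to 0.07.

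Some genes of cholesterol and fatty acid synthesis fell with age. Of 26 cholesterol synthesis genes, 10 fell and none rose, with 14 fallen when adjusted over the list alone and a median log2 fold of -0.50. The synthase Hmgcs1 fell from 277 to 150.3 FPKM, the kinase Pmvk from 73.3 to 38.0 and Fdps from 235 to 138. Of 22 fatty acid synthesis genes, 9 fell and none rose, with 13 fallen when adjusted over the list alone and a median of -0.52. The citrate lyase Acly fell from 101 to 48.8 FPKM, the carboxylase Acacb from 12.9 to 6.33, the phosphatidate phosphatase Lpin1 from 21.03 to 10.8 and Pnpla3 from 1.11 to 0.131. Fasn, named after its values were seen, was at 125 and 55.9 FPKM with a q-value of 0.101 in the authors' deposited table. Both medians lay below their random ranges of -0.14 to 0.08 and -0.16 to 0.08. The fatty acid oxidation list went both ways, with 3 genes risen and 3 fallen of 31 (4 and 3 adjusted over the list alone) and a median of 0.05 inside the random range. The omega-hydroxylases Cyp4a14, Cyp4a31 and Cyp4a10 fell, from 173 to 39.5, from 11.9 to 5.10 and from 144 to 87.6 FPKM, and the pantetheinase Vnn1 rose from 19.6 to 34.7.

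Bile acid, glucose and nitrogen metabolism changed in a few members each. Of 24 bile acid genes, 4 rose and 2 fell, and adjusted over the list alone 5 rose and 4 fell. Cyp39a1 fell from 30.0 to 7.19 FPKM, and beside Cyp7b1 the transporters Slco1b2 and Slc10a2 rose from 581 to 1012 and from 11.4 to 20.1. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 38.8 and 53.8 FPKM, with a q-value of 0.965 in the authors' deposited table. The bile acid median of 0.09 lay just above its random range of -0.16 to 0.06 and inside the range of unmatched random lists; with no minimum on FPKM it was 0.07 and inside its range. In glucose and glycogen metabolism 1 gene rose and 3 fell of 24 (1 and 5 adjusted over the list alone), the median being -0.26 against a random range of -0.15 to 0.08. The kinase Pfkfb3 rose from 1.79 to 3.51 FPKM, while Khk fell from 295 to 199, Ppargc1a from 2.48 to 1.48 and the glucose-6-phosphate transporter Slc37a4 from 88.4 to 63.1. In urea cycle and amino acid breakdown 1 gene rose and 4 fell of 34, the same numbers as when adjusted over the list alone, with a median of -0.24 against -0.15 to 0.04. The ornithine aminotransferase Oat rose from 236 to 729 FPKM, and Gldc, Hal and Ass1 fell, from 51.7 to 28.3, from 169 to 101 and from 1019 to 637.

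Zonation genes, which mark hepatocytes by their place between portal and central vein, changed in part, with the called pericentral genes risen and all but 1 of the called periportal genes fallen. Of 18 pericentral genes, 6 rose and none fell, and 10 rose when adjusted over the list alone; the median was 0.42 against a random range of -0.17 to 0.10. Of 18 periportal genes, 7 fell and 1 rose, and adjusted over the list alone 8 fell and 2 rose; the median was -0.41 against -0.17 to 0.09. Oat, the glutamate transporter Slc1a2 and the aldehyde dehydrogenase Aldh3a2 rose on the pericentral side, the last 2 from 22.2 to 53.01 and from 87.7 to 203 FPKM, and the R-spondin receptor Lgr5 rose from 1.13 to 2.94. Cyp2e1, named after its values were seen, was at 2631 and 4140 FPKM, with a q-value of 0.0826 in the authors' deposited table. On the periportal side E-cadherin, Cdh1, fell from 14.1 to 6.49 FPKM along with Gldc and Hal, and the immunoglobulin transporter Pigr rose from 184 to 343. Without members shared with the metabolic lists, 5 of 14 pericentral genes rose, and 3 of 7 periportal genes fell and 1 rose.

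Some drug-metabolizing enzymes of phase I and of conjugation were called, and the difference between these groups was not tested. Of 31 phase I enzymes, 2 rose and 1 fell (3 and 2 adjusted over the list alone), with a median of 0.0047 inside the random range. Cyp2a5 rose from 118 to 283 FPKM and the retinoic acid hydroxylase Cyp26a1 from 6.01 to 9.13, and Cyp2c55 fell from 22.3 to 11.2. Of 36 conjugation and glutathione enzymes, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.10 above the random range of -0.14 to 0.05. The glutathione transferase Gsta1 rose from 4.52 to 25.2 FPKM, Gsta2 from 13.1 to 24.2 and the nicotinamide methyltransferase Nnmt from 40.1 to 103, and the sulfotransferase Sult1a1 fell from 321 to 186.

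Many immune genes rose with age, among them those of MHC class II. Of 22 antigen presentation genes, 10 rose and none fell, with 14 risen when adjusted over the list alone and a median log2 fold of 0.62 against a random range of -0.13 to 0.10. H2-Ab1, on chromosome 17 at 34263209 to 34269418, rose from 9.13 to 61.4 FPKM, H2-Eb1 from 7.13 to 48.5, H2-Aa from 20.8 to 129.7, and the invariant chain Cd74, on chromosome 18 at 60803848 to 60812646, from 27.8 to 150.5. Of 11 T and NK cell markers, 8 rose and none fell, with 9 risen when adjusted over the list alone and a median of 0.92 against -0.20 to 0.23. Beside Ccl5, Nkg7 rose from 0.846 to 4.95 FPKM, the T cell receptor chain Trac from 0.715 to 3.77 and Cd3g from 0.807 to 3.56. Only 11 of the 22 members of this list passed the filter. Nkg7, Trac and Cd3g were under 1 FPKM in young liver and passed the filter only through adult values, so they could only be higher. Of 36 interferon-stimulated genes, 14 rose and 4 fell, and adjusted over the list alone 15 rose and 10 fell. The median of 0.05 lay inside the random range, but with a minimum of 5 FPKM it was 0.30 and above its range. Cxcl9 rose from 12.7 to 44.0 FPKM, the GTPase Igtp from 30.4 to 86.3, Ifi27l2b from 4.60 to 14.3 and Cxcl10 from 8.28 to 22.97. The 4 that fell, named after their values were seen, were Isg15, from 36.0 to 18.6 FPKM, Rsad2, from 9.51 to 5.38, Ddx58, from 14.3 to 9.10, and Ifit3, from 11.6 to 7.85.

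Markers of other immune cells and acute phase genes changed in part. Of 17 Kupffer cell and macrophage markers, 3 rose (4 adjusted over the list alone), Marco, from 13.8 to 25.5 FPKM, Cd5l, from 63.9 to 96.7, and Ly86, from 10.4 to 15.9; the median was 0.20 against a random range of -0.13 to 0.13. Of 5 B and plasma cell markers, 2 rose (4 adjusted over the list alone), Ighm, from 10.5 to 18.5 FPKM, and Igkc, from 44.6 to 70.9, while the B cell receptor gene Cd79b, named after its values were seen, was at 1.23 and 1.196 FPKM; the median was 0.60 against -0.26 to 0.27. Of 8 neutrophil and monocyte markers, 2 rose (4 adjusted over the list alone), Ccr2, from 0.926 to 2.44 FPKM, and Lyz2, from 82.8 to 115. Their median of 0.38 lay above the random range of -0.22 to 0.24, but it was -0.0163 with no minimum on FPKM and 0.019, inside its range, with a minimum of 5. None of 4 dendritic cell markers was called, by either adjustment, with Bst2 at 284 and 268 FPKM and Irf8 at 2.01 and 3.99; their median was 0.20, inside the random range. Acute phase genes went both ways, with 7 risen and 4 fallen of 27 (7 and 8 adjusted over the list alone). The serum amyloids Saa2, Saa1 and Saa3 rose from 30.2 to 141, from 85.8 to 276 and from 13.2 to 41.4 FPKM, while the hepcidin genes Hamp2 and Hamp and the metallothioneins Mt1 and Mt2 fell. Hamp, Mt1 and Mt2, named after their values were seen, went from 473 to 288, from 104 to 36.3 and from 66.3 to 21.97 FPKM. The median of this list was negative, -0.15, although more members were called risen than fallen. It lay inside the random range but below that of unmatched random lists, and with a minimum of 5 FPKM it was -0.21 and below its range.

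Circadian clock genes changed in both directions. Of 21, 7 rose and 5 fell, and adjusted over the list alone 12 rose and 5 fell. Dbp, on chromosome 7 at 45705088 to 45710155, had a log2 fold of 3.22. The nuclear receptors Nr1d2 and Nr1d1 rose from 8.68 to 27.5 and from 6.89 to 17.3 FPKM, and the transcription factor Tef rose from 8.997 to 24.7. Among those that fell, named after their values were seen, were Arntl, from 10.2 to 4.11 FPKM, Npas2, from 2.01 to 0.513, Cry1, from 5.77 to 3.28, and Nfil3, from 16.1 to 10.5. The q-values of Arntl, Npas2 and Cry1 in the authors' deposited table were 0.00189, and that of Nfil3 was 0.00494. The list median was 0.41 against a random range of -0.12 to 0.14. The labels give no time of day at sacrifice for either age.

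Stress and housekeeping lists showed small or divided changes. In the p53 and senescence list 3 genes rose and 2 fell of 21 (3 and 3 adjusted over the list alone), with a median of 0.10 inside the random range; with no minimum on FPKM it was 0.13 and above its range. The cell cycle inhibitor Cdkn1a fell from 15.7 to 5.69 FPKM and Bbc3 from 6.72 to 3.71, while the stress cytokine Gdf15 rose from 2.87 to 6.60 and the receptor Eda2r from 0.280 to 1.02. In the heat shock and ER stress list 3 rose and 3 fell of 33 (3 and 7 adjusted over the list alone), with a median of -0.11 inside the random range but below that of unmatched random lists; with a minimum of 5 FPKM it was -0.18 and below its range. Hspb1 rose from 3.46 to 9.70 FPKM, Atf3 from 0.552 to 1.95 and Hspa1b from 2.499 to 4.65, and the chaperone Calr fell from 461 to 310. None of 36 ribosomal protein genes was called, and none was when adjusted over the list alone, with Rplp1 at 1061 and 993 FPKM and Rps24 at 574 and 486; their median was -0.16, inside the random range but below that of unmatched random lists. None of 33 oxidative phosphorylation genes was called by either adjustment, with Cox7b at 1449 and 1417 FPKM and Ndufa4 at 1088 and 992. Their median of -0.22 lay below the random range of -0.17 to 0.03.

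Globin transcripts fell. Of 9 erythroid genes, 5 fell and none rose, and adjusted over the list alone 5 fell and 1 rose. The median was -1.41 against a random range of -0.22 to 0.18, and the mean log2 fold was -0.89. Of the 9 genes, 5 were lower and 4 higher in adults. The median is therefore the value of the least fallen of the 5 and not a shift of the whole list. Hba-a1, Hba-a2, Hbb-bt and Hbb-bs fell from 277 to 50.2, from 162 to 36.6, from 53.2 to 17.0 and from 634 to 235 FPKM. Alas2, the heme synthesis enzyme of erythroid cells, named after its values were seen, was at 55.3 and 73.2 FPKM with a q-value of 0.368 in the authors' deposited table. Of 6 adipocyte genes, 2 rose, while adjusted over the list alone 3 rose and 1 fell. The lipid droplet gene Cidec rose from 0.783 to 4.09 FPKM and Cfd from 0.0794 to 1.68. The median of 0.38 lay above the random range of -0.25 to 0.27, but with a minimum of 5 FPKM it was 0.30 and lay inside its range. Neither of the 2 pancreas genes compared was called by either adjustment, with Cela1 at 21.9 and 20.9 FPKM and Cela2a at 1.16 and 0.803; their median was -0.16, inside the random range.

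**Figure D3:**
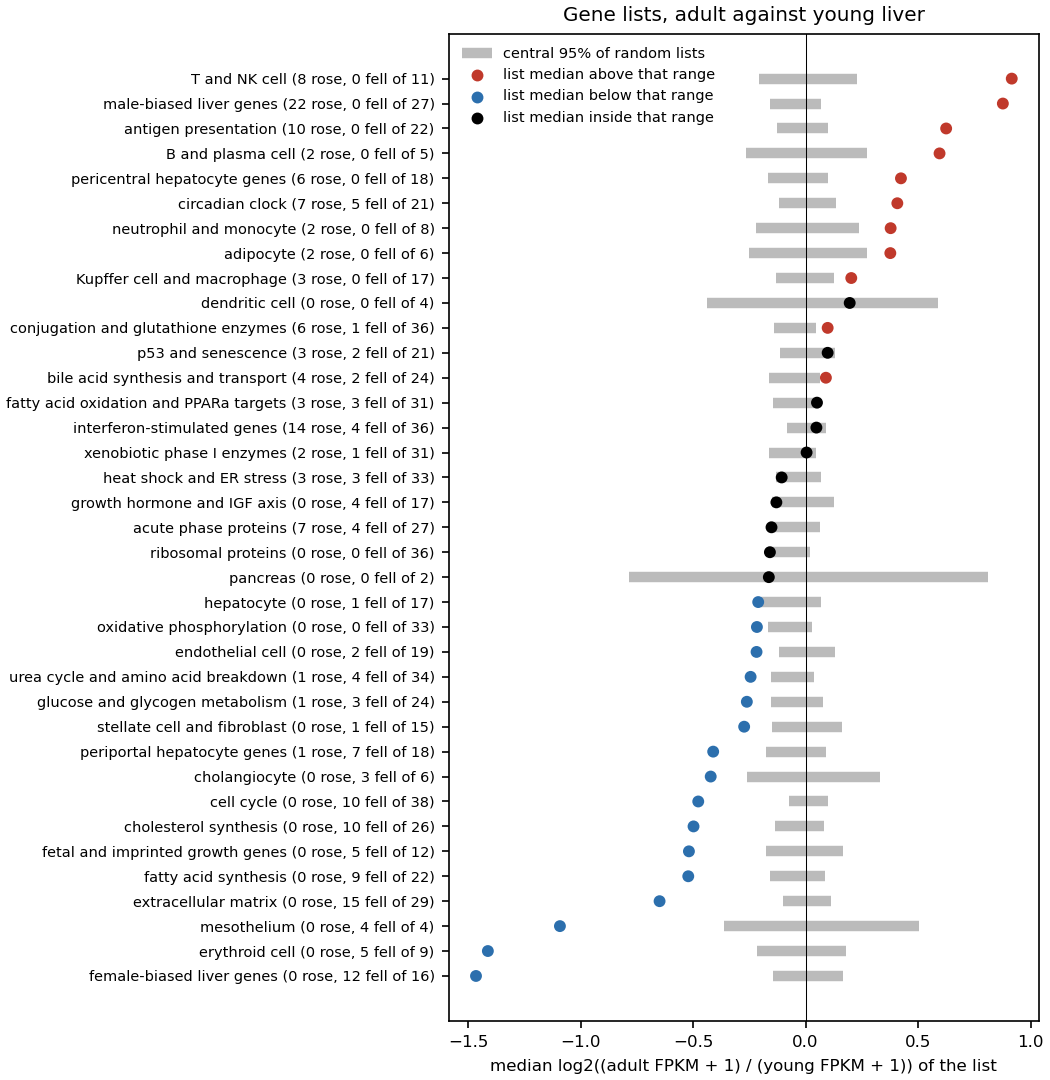
Each dot is the median log2((adult FPKM + 1)/(young FPKM + 1)) of 1 of the 37 gene lists, with the numbers of risen, fallen and compared members beside its name, and each grey bar spans the central 95% of 10000 random lists matched on expression. In all, 11 lists lay above and 16 below their bars, from 0.92 for T and NK cell markers to -1.46 for female-biased genes.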

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

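The counts depended on how strictly genes were chosen. With a minimum of 5 FPKM, 546 genes were called (293 risen, 253 fallen), with an added 2-fold minimum 231 (150 risen, 81 fallen), and with a q threshold of 0.01 608, of which 260 fell. With no FPKM filter 1111 genes were called, with a q threshold of 0.1 1065, and with q recomputed over the genes past the filter 955; each of these 3 sets held all 877 calls. Centring the folds, rescaling to TPM, rescaling without the 50 highest genes and a pseudocount of 0.1 left every call and direction as it was, and moved the median of all genes by at most 0.013 on the log2 scale; the authors' q was kept in them, so they could change only a direction and do not show whether the counts depend on scaling. The share of risen genes among the calls was 53.5% as reported and 64.9% with the 2-fold minimum. Of the 37 lists, 27 lay outside the range of random lists as reported, and 25 to 30 did under the 5 alternatives. The median of fetal and imprinted genes changed sign, to 0.048, with a minimum of 5 FPKM, and that of neutrophil and monocyte markers, to -0.0163, with no filter; the cause was not tested. With a minimum of 5 FPKM the T and NK cell, dendritic cell, pancreas and mesothelium lists kept fewer than 2 genes and gave no median. No paired analysis was possible because the deposited table holds 1 value per age group; for the same reason the planned runs leaving out each library, with other count tests and with list tests across libraries were not run, and no other split of the 6 samples could be counted. Depth per library is unknown, and genes near 1 FPKM, among them T, NK and B cell markers, are the least certain.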

Other observations

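Genes outside the 37 lists changed as well. Inflammatory chemokines rose on chromosome 11, where Ccl3 went from 0.182 to 3.09 FPKM and Ccl4 from 0.462 to 5.58. Serpine2, a protease inhibitor, rose from 0.789 to 8.56 FPKM, the macrophage elastase Mmp12 from 0.563 to 4.51, S100a4 from 1.47 to 7.49 and the carboxylesterase Ces2c from 38.3 to 142. The ecto-nucleotidase Nt5e fell from 11.7 to 2.69 FPKM. Each of these genes, named after its values were seen, had a q-value of 0.00189 in the authors' deposited table.

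The tests below were chosen after the results had been seen, except those of Xist, of the further interferon gamma targets, of neighbouring genes and of immediate early genes, which were set down before their values were read. None compares libraries.

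Of 21 Mup genes 17 rose, while 12 of 16 female-biased genes fell. Reads shared between Mup copies cannot be the whole of it, since the sum over all 21 Mup genes was 2.67 times as high in adults, at 15061 FPKM in young and 40189 in adult liver. Female mice in the young pools are argued against by Xist, at 0.0048 FPKM in young and 0.0052 in adult liver, and by the Y-linked Ddx3y, at 27.6 and 35.3 FPKM. Maturation of the male liver pattern between weaning and adulthood is a candidate explanation, since male-biased genes other than Mup had a median log2 fold of 0.73 and lay above random lists; it remains a hypothesis found on the same data.

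H2-Ab1, H2-Eb1, H2-Aa and Cd74 rose 5.41-fold to 6.81-fold by the plain ratio of FPKM. A lower share of hepatocytes would raise the markers of every other cell type alike only if the mix of those cells stayed the same. The endothelial list had a median log2 fold of -0.22, while T and NK markers stood at 0.92. Other lists also went both ways, with Kupffer cell and macrophage markers at 0.20 and stellate cell and fibroblast markers at -0.27. The hepatocyte list itself, at -0.21, lay below its random range. With an unchanged mix of the other cells, a lower share of hepatocytes is therefore argued against. The endothelial and stellate medians were negative and below their random ranges, where this explanation would have them raised. With a changed mix, a lower share of hepatocytes is not set aside by these values. A response of the interferon gamma type may contribute. Among 12 further targets, 8 rose and none fell, with a median of 0.85 above the random range of -0.17 to 0.17. These 8 are not independent, since Gbp4, Gbp5, Gbp8, Gbp9 and Gbp11 are of the same gene family. Cd274, Gbp5 and Socs1 were under 1 FPKM in young liver, at 0.842, 0.823 and 0.242. Of 12 further targets of type I interferon none was called, and the median was 0.05. More B cells stay open, as the B and plasma cell list, at a median of 0.60, rested on 5 genes and Cd79b was at 1.23 and 1.196 FPKM, near the filter, and so does an effect of age on the immune cells of the liver, which was not tested.

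The called clock genes moved in opposite directions: the 5 genes set to the arm of Arntl fell and the 7 others rose, so that all 12 followed their arm. The arms were set after the results had been seen, and every gene outside that of Arntl was counted in the other. This count therefore adds little to the directions themselves. A different time of day at sacrifice and an effect of age on the clock would both look like such opposite movement. They cannot be told apart, since no label gives the time. Lipid and cholesterol synthesis genes, which follow feeding and the clock, may be affected as well; this was not tested.

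Called genes lay side by side on the chromosomes. In 1 run of 10 neighbouring tested genes on chromosome 4 between 60218621 and 61519531, all 10 rose, 9 of them Mup genes. The highest run in 10000 shuffled gene orders held 7 (permutation p = 0.0001, the smallest these can give). The shuffles treat genes as independent, but neighbouring Mup copies can share reads. This p-value therefore adds little to the rise of the Mup genes given above. Further runs on chromosome 11, with Ccl genes, and on chromosome 4, with other Mup genes, held 6 risen genes each. Runs of 5, with MHC class II genes on chromosome 17, Gbp genes on chromosome 5, Ms4a genes on chromosome 19, Slam family genes on chromosome 1 and Iigp1 and Cd74 on chromosome 18, do not stand out singly, since 5 is also the 95th percentile of the highest run in the shuffled orders. Fallen genes reached at most 5 in such a run, on chromosome X with Armcx3, Bhlhb9, Tceal8, Wbp5 and Ngfrap1 (permutation p = 0.0531). The immediate early gene Nr4a1, named after its values were seen, rose from 0.498 to 7.78 FPKM. Of 12 further immediate early genes, 4 rose, Fos, Jun, Junb and Socs3, and none fell. Their median log2 fold was 0.24 against a random range of -0.14 to 0.18.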
